A study of Homo sapiens with 12 samples.

How the data were processed

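Total RNA from 12 cultures of BEAS-2B cells was hybridised to Affymetrix Human Transcriptome arrays after biotin labelling from 6 µg of RNA, per the labels' protocols and the header of the probe table. Cells attached for 24 h and then stayed for 24 h in medium only or in medium with silica nanoparticles of 40, 60 or 200 nm at 25 µg/ml, with 3 arrays per group. The labels call the arrays of a group biological replicates and give no further detail on separate cultures or processing days, so each p-value measures only the spread between these samples.

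The deposited table holds summarized probe set signals as log2 values, read from their range of 2.56 to 19.93, and MAS5 is the only method named, per the submitters' processing notes, without a version. The notes do not state how arrays were scaled to each other. The medians and quantiles of the arrays differ, so the deposited values were not quantile normalized over all rows. No genome build is named, and no coordinates are given here.

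Of 70523 rows in the table, 67528 are transcript clusters. The other 2995 rows were left out of the comparisons: 23 background controls, 155 ERCC controls, 1344 other controls, 1465 probe selection regions or junctions and 8 spike-in controls. The plan had named only the control rows with the AFFX prefix, so this exclusion is wider. The 40 percent of transcript clusters with the lowest mean over the 12 arrays were dropped, at a limit of 3.90, which left 40517 probe sets. Of these, 16698 name 1 gene, 1166 name several and 22653 name none. A gene was represented by its brightest probe set, which gave 15836 genes, 279 of them with several probe sets. The probe table names genes for 25324 probe sets, 23781 with a single symbol and 1543 with several, and 0 symbols needed an update. Levels of 44 probe sets of some sex-linked genes are left unnamed, while other sex-linked genes, such as SAT1 on the X chromosome, are named.

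The comparisons, tests, gene lists, naming rule and most of the other settings tried were fixed before the data were examined. The plan foresaw an offset of 16 before taking logarithms unless the values were already log2; they were, and they were used as deposited. Linear models with 1 mean per group over all 12 arrays were fitted with limma 3.58.1 in R 4.3.3, with moderated statistics and an intensity trend in the prior variance. P-values were two-sided and adjusted by Benjamini-Hochberg over the 40517 probe sets, with a threshold of 0.05. The 6 comparisons were each size against control and each pair of sizes, with moderated F tests for any difference among the 4 groups and among the 3 sizes. The number of arrays limits the precision; the median standard error of a log2 change was 0.149. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

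The named genes are, for each size against control, the 10 rising and 10 falling genes with the largest change among those past the threshold in which all 3 exposed arrays lie on the same side of all 3 control arrays. For a size against another size the rule takes 5 and 5. Where none passed, the 5 genes with the smallest p are given as values. Each list adds up to 4 members, and HMOX1, NQO1, MT1X, HSPA5, DDIT3, HSPA1A, IL6, CXCL8, CDKN1A, HMGCS1, CYP1A1 and SQSTM1 are always named; CYP1A1 was below the filter.

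The 27 gene lists hold 578 entries, 476 of them measured. They cover NRF2 antioxidant targets, metallothioneins and zinc export, the ATF4 integrated stress response, endoplasmic reticulum chaperones, cytosolic heat shock, NF-kB cytokines and targets, inflammasome and pyroptosis, the type I interferon response, p53 targets, mitosis, DNA replication, cholesterol synthesis and uptake, lysosome, autophagy, endocytosis and caveolae, aryl hydrocarbon receptor targets, hypoxia, immediate early genes, mesenchymal and matrix genes, epithelial junctions and keratins, oxidative phosphorylation and cytosolic ribosomal proteins. Markers of airway basal cells, airway secretory and ciliated cells, fibroblasts, leukocytes and endothelial cells stand for other cell types. The 25 lists with at least 5 measured genes were tested with camera in limma with its preset inter-gene correlation of 0.01, which compares a list with all other genes, and adjusted over the 25 lists. The same test with a correlation estimated per list, and fry, which tests whether a list's genes move on balance 1 way and makes no comparison with other genes, were run beside it.

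Pairing by replicate number was checked from the correlation of same-numbered arrays, each centred on its group mean. Over the 9 same-numbered pairs of exposed arrays every correlation was above 0.1, from 0.238 to 0.841, so the number was taken to pair the exposed arrays, although the labels do not say what it marks. Over the 9 pairs with a control array it ran from -0.466 to 0.598, with 3 above 0.1, so controls were not paired. The highest correlation between 2 arrays was 0.994, and 0 columns were identical.

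Changes that the 3 sizes share were compared with 100 simulated sets of unchanged groups that use the same controls. The scripts were tested on simulated data for 40 nm against control over 40517 probe sets: the fit recovered 64.2% of probe sets raised by 1 on the log2 scale, 94.0% of those raised by 2 and 98.5% of those raised by 4, with 9 unchanged probe sets called. Over 15836 genes, the 1 raised list was called and 0 of the other lists. The simulated noise was independent between probe sets and between arrays. These rates therefore do not carry over to the real arrays, whose genes vary together along a main axis.

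The other settings tried were an offset of 1 or 64, quantile normalization, centring on array medians, no filter or a filter of 60 percent, a prior variance without trend or robust, array weights, the replicate number as a block, only the arrays compared, 1 probe set per gene, a fold change of at least 2, and leaving out each array in turn. More were added after the data had been seen: the spike-in mean as a covariate, cyclic loess normalization, array weights estimated gene by gene, leaving out the 3 arrays with the lowest spike-in mean, and the replicate block with only the 9 exposed arrays.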

Results

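Gene expression was measured on 12 arrays of BEAS-2B cells, an immortalised line from human bronchial epithelium. Control cells received medium only, and exposed cells received silica nanoparticles of 40, 60 or 200 nm for 24 h at the same mass per volume, 25 µg/ml, with 3 arrays in each of the 4 groups. The deposited values are on a log2 scale, and the array medians ran from 3.90 (40 nm replicate 1) to 4.19 (control replicate 1). Every change below is a log2 difference with its standard error from limma, and each group mean is given with its SD over 3 arrays. The arrays also differed along an axis, the first principal component, that crossed the groups only in part. Control replicates 1 and 2 scored 98.1 and 89.7 on it, above every exposed array (highest 39.9, 200 nm replicate 2). Control replicate 3 scored -23.9, among the exposed arrays. The first principal component held 66.1% of the variance and followed the mean of the 8 spike-in control rows over 12 arrays, with Pearson r 0.906 (permutation p 5e-05) and Spearman rho 0.867 (permutation p 0.00063), 1 relation tested. Without 40 nm replicate 1 and 60 nm replicate 1, the arrays farthest from the median spike-in mean, r was 0.877. The spike-in mean was 7.64, 7.92 and 7.99 in replicate 1 of the 40, 60 and 200 nm groups and 8.87 to 9.47 on the other 9 arrays.

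**Figure D1:**
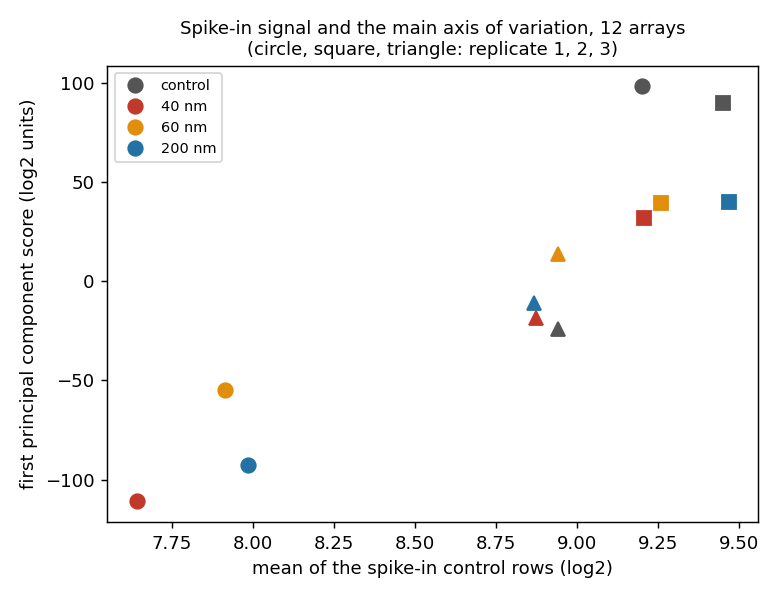
Score on the first principal component (log2 units) against the mean of the 8 spike-in control rows (log2) for 12 arrays, coloured by group, with the replicate number as the marker. Replicate 1 of the 40, 60 and 200 nm groups had the lowest spike-in means, 7.64, 7.92 and 7.99.

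The comparison of 40 nm particles with medium only asks which genes responded to the smallest particles. MMP1, the interstitial collagenase, rose from 4.27 ± 0.11 in control cells to 9.61 ± 0.60 at 40 nm, a change of 5.34 (SE 0.31, limma adjusted p 0.000135). MMP3, the matrix protease stromelysin, rose by 2.07 (SE 0.19, limma adjusted p 0.00497). The inflammatory cytokine IL1B rose by 2.25 (SE 0.25, limma adjusted p 0.0170), from 6.02 ± 0.27 to 8.27 ± 0.45, and the cytokine IL6 rose by 1.20 (SE 0.15, limma adjusted p 0.0335). FBXO32, a subunit of a ubiquitin ligase, rose by 1.58 (SE 0.13, limma adjusted p 0.00294), and SAT1, an enzyme of polyamine breakdown, rose by 1.10 (SE 0.10, limma adjusted p 0.00566). RND3 rose by 2.22 (SE 0.27), and ITGA2, a collagen-binding integrin subunit, rose by 1.99 (SE 0.23). G0S2, an inhibitor of triglyceride breakdown, rose by 1.53 (SE 0.20), KTN1, a kinesin-binding membrane protein, by 1.08 (SE 0.14), and DDIT3, a transcription factor of the stress response, by 0.77 (SE 0.10), with limma adjusted p from 0.0269 to 0.0450 for these 5 genes. The microRNA gene MIR1264 fell by 0.99 (SE 0.13, limma adjusted p 0.0410). In each of these 12 genes all 3 arrays at 40 nm lay on the same side of all 3 control arrays. The control levels of MMP1 (4.27), MMP3 (4.38), ITGA2 (4.39), DDIT3 (4.56) and SAT1 (4.84), and the level of MIR1264 at 40 nm (4.25), lay inside the range of the background row means, 3.21 to 4.89. Background therefore limits how exactly the sizes of these 6 changes are known. The control level of IL6 (4.91) lay just above that range, so its change is not free of this limit.

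With these 12 genes, 17 of 40517 probe sets passed the test at 40 nm, 16 higher and 1 lower, and 5678 had an unadjusted p under 0.05 (1757 higher, 3921 lower), where chance gives 2025.85. The median change over all probe sets was -0.087. The other 5 passing probe sets have no symbol in the probe table and are named here after their values were seen: TC11003312.hg.1 (6.73), TC11003311.hg.1 (5.02), TC01004998.hg.1 (2.93), TC0X001624.hg.1 (2.45) and TC05003160.hg.1 (1.68). The count depended on single arrays: it was 548 without control replicate 3, 5 without control replicate 2, 8 without control replicate 1, 9 without 40 nm replicate 3, 10, 9 and 7 without 60 nm replicates 1, 2 and 3, and 9 and 7 without 200 nm replicates 2 and 3. With only the 6 arrays compared it was 2, and MMP1 kept its call there with a limma adjusted p of 0.0488.

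**Figure D2:**
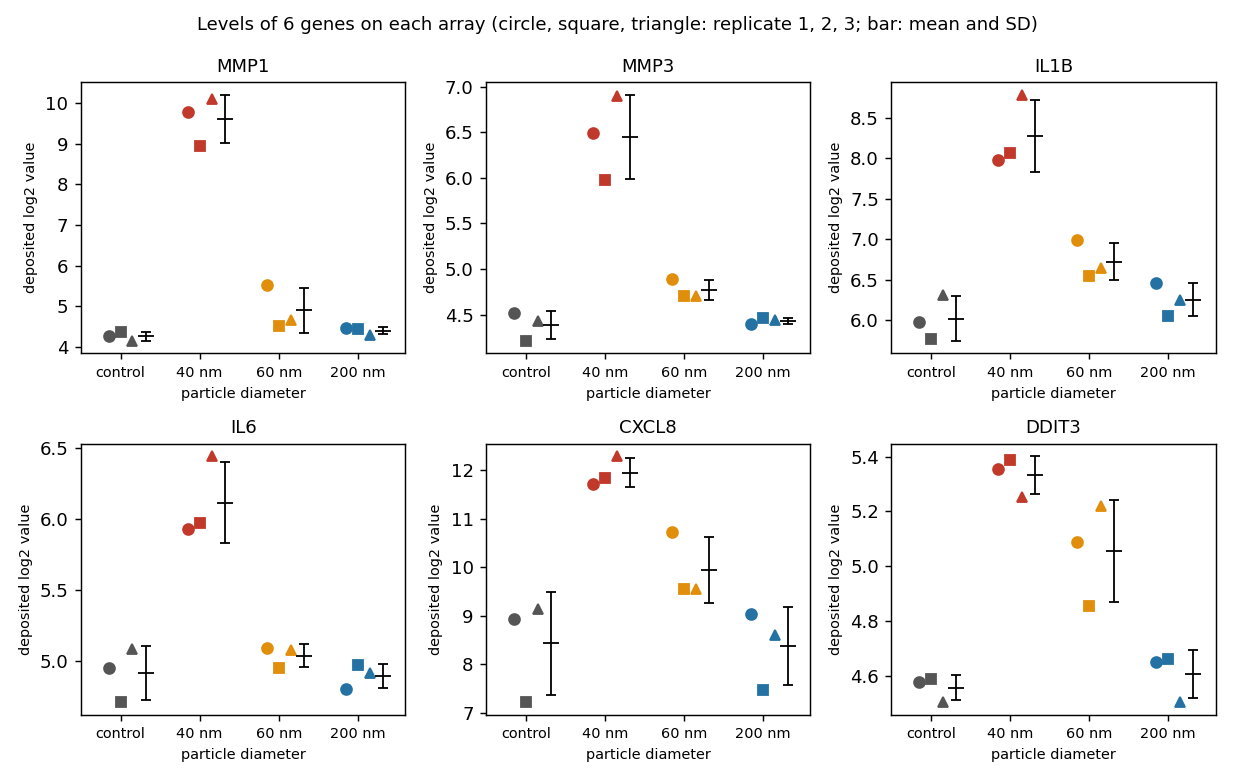
Deposited log2 values of MMP1, MMP3, IL1B, IL6, CXCL8 and DDIT3 on each of the 12 arrays by group, with the replicate number as the marker and the bar as mean and SD (n = 3). MMP1 lies at 9.61 ± 0.60 at 40 nm and at 4.27 ± 0.11 in control cells.

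Several gene groups stood higher at 40 nm than in control cells. Of 23 measured NF-kB cytokines and targets, 22 had positive changes with a mean of 0.90, and the list mean relative to control was 0.90 ± 0.18 at 40 nm against an SD of 0.18 in controls (camera adjusted p 3.55e-11). IL1B and IL6 passed over all genes and 11 passed when adjusted over the list alone. The neutrophil chemokine CXCL8 had the largest value of this list, 3.52 (SE 0.58), without passing over all genes (limma adjusted p 0.113). Of 19 p53 targets, 18 had positive changes with a mean of 0.45 (camera adjusted p 3.94e-05); 0 passed over all genes by limma and 1 when adjusted over the list alone. The values were 1.27 for MDM2, which degrades p53, 1.93 for the cyclin CCNG1 and 0.60 for the cell cycle inhibitor CDKN1A. Of 25 genes of the ATF4 integrated stress response, 23 were positive with a mean of 0.70; DDIT3 passed over all genes and 5 when adjusted over the list alone. The ATF4 list had a camera adjusted p of 2.95e-08 (adjusted p = 0.0504 with an estimated correlation). Of 15 cytosolic heat shock genes, 14 were positive with a mean of 1.03, led by the chaperone genes DNAJA1 at 3.01 (SE 0.91), HSP90AB1 at 2.74 (SE 0.75) and HSP90AA1 at 2.67 (SE 0.70). None of them passed over all genes, 5 passed when adjusted over the list alone, and the list had a camera adjusted p of 4.69e-05 (adjusted p = 0.1 with an estimated correlation). HSPA1A stood at 0.97 (SE 0.54).

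Of 28 type I interferon response genes, 24 were positive at 40 nm with a mean of 0.45, among them IFIT3 at 1.43 (SE 0.32), OAS2 at 1.34 (SE 0.39) and the RNA sensor RIGI at 1.01 (SE 0.26). None passed over all genes and 9 when adjusted over the list alone, with a camera adjusted p of 5.28e-09 (adjusted p = 0.0947 with an estimated correlation). Of 25 lysosome genes, 24 were positive with a mean of 0.81, among them PSAP at 2.13, LAMP2 at 1.95, the cholesterol transporter NPC1 at 1.93 and the protease CTSL at 1.69. None passed over all genes and 12 when adjusted over the list alone, with a camera adjusted p of 5.28e-09 (adjusted p = 0.127 with an estimated correlation). All 8 metallothionein and zinc export genes were positive with a mean of 0.47, with MT1F at 0.93 and MT1X at 0.78. None passed over all genes and 3 when adjusted over the list alone, with a camera adjusted p of 0.000437 (adjusted p = 0.127 with an estimated correlation). Of 25 autophagy genes, 21 were positive with a mean of 0.46, with WIPI1 at 1.69 and the cargo receptor SQSTM1 at 0.93, and 1 passed when adjusted over the list alone. The autophagy list had a camera adjusted p of 0.000437 (adjusted p = 0.288 with an estimated correlation). Of 20 hypoxia genes, 16 were positive with a mean of 0.43, with BNIP3L at 1.33 and LOX at 1.23, and 1 passed when adjusted over the list alone. The hypoxia list had a camera adjusted p of 0.000629 (adjusted p = 0.140 with an estimated correlation).

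Other stress and growth groups also passed at 40 nm with the preset correlation. Of 24 NRF2 antioxidant targets, 19 were positive with a mean of 0.26, with GSR at 0.93, HMOX1 at 0.55 (SE 0.16) and NQO1 at -0.00 (SE 0.27), and the camera adjusted p was 0.00840 (adjusted p = 0.127 with an estimated correlation). Of 21 endoplasmic reticulum chaperones, 17 were positive with a mean of 0.54, with CANX at 2.43 and HSPA5 at 2.32, and the camera adjusted p was 0.00462 (adjusted p = 0.372 with an estimated correlation). Of 24 mesenchymal and matrix genes, 17 were positive with a mean of 0.54; MMP1 was the 1 that passed over all genes and also when adjusted over the list alone, and the camera adjusted p was 0.0154 (adjusted p = 0.372 with an estimated correlation). Of 19 immediate early genes, 15 were positive with a mean of 0.08, with CCN1 at -1.04 and IER3 at 0.49; 1 passed when adjusted over the list alone, and the camera adjusted p was 0.0198 (adjusted p = 0.331 with an estimated correlation). Of 27 mitosis genes, 21 were positive with a mean of 0.61, with PRC1 at 1.55 and TPX2 at 1.38, and the camera adjusted p was 0.00398 (adjusted p = 0.380 with an estimated correlation). Of 31 DNA replication genes, 23 were positive with a mean of 0.35, with CDC6 at 1.30, MCM6 at 1.27 and TK1 at -1.37, and the camera adjusted p was 0.0154 (adjusted p = 0.523 with an estimated correlation). The 6 measured airway secretory and ciliated cell markers had group means inside the range of the background rows. Their mean change was -0.13, with SCGB1A1 at -0.25 and SPDEF at -0.21, against a median of -0.09 over all probe sets. The camera adjusted p was 0.0455 (adjusted p = 0.288 with an estimated correlation). This is a shift of signal at background level and is not read as a change of these markers. Adjusted over the list alone, 0 genes of the NRF2, chaperone, mitosis, DNA replication and secretory lists passed. The list mean on control replicate 3 lay above that on 40 nm replicate 2 for the NRF2, chaperone, mesenchymal, mitosis and DNA replication lists. The same held for the autophagy and hypoxia lists. The mitosis score fell as the spike-in mean rose within groups, with a slope of -0.68 (SE 0.12). With the spike-in mean as a covariate the mitosis, DNA replication, mesenchymal and secretory lists had camera adjusted p of 0.127, 0.268, 0.191 and 0.0639.

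The remaining lists did not pass at 40 nm, and 0 of their genes passed over all genes or when adjusted over the list alone. The mean was 0.41 over 22 endocytosis and caveolae genes (RAB7A 2.45, CLTC 2.19; camera adjusted p 0.0683) and 0.28 over 9 inflammasome and pyroptosis genes (TXNIP 1.14, CASP4 0.97; camera adjusted p 0.215). It was 0.08 over 19 cholesterol synthesis and uptake genes (CYP51A1 1.51, HMGCS1 0.88, TM7SF2 -1.06; camera adjusted p 0.861). Over 16 cytosolic ribosomal protein genes it was 0.07 (RPS4X 0.56, RPL10A 0.37; camera adjusted p 0.594). In 17 epithelial junction and keratin genes (DSP 1.33, DSG2 1.16; mean 0.12, median -0.14), 25 oxidative phosphorylation genes (UQCRC2 2.02, NDUFS1 1.11; mean 0.09, median -0.06) and 7 leukocyte markers (CD68 1.23, CD163 -0.16; mean 0.12, median -0.10) the mean was positive while the median and the test direction were negative, with camera adjusted p of 0.502, 0.948 and 0.694. The means were -0.01 over 6 airway basal cell markers (ITGA6 1.03, ITGB4 -0.90; camera adjusted p 0.594) and -0.16 over 7 fibroblast markers (PDGFRB -0.44, THY1 -0.34; camera adjusted p 0.129). Only 4 aryl hydrocarbon receptor targets (CYP1B1 1.15, TIPARP -0.02; mean 0.43) and 4 endothelial cell markers (ENG 0.63, CDH5 -0.13; mean 0.08, median -0.09) were measured, and they are given as values without a test. In all, 16 of 25 lists passed with the preset correlation, 15 higher and 1, the secretory markers at background level, lower. With an estimated correlation 2 of them held: NF-kB targets and p53 targets, each with an adjusted p of 0.0185.

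**Figure D3:**
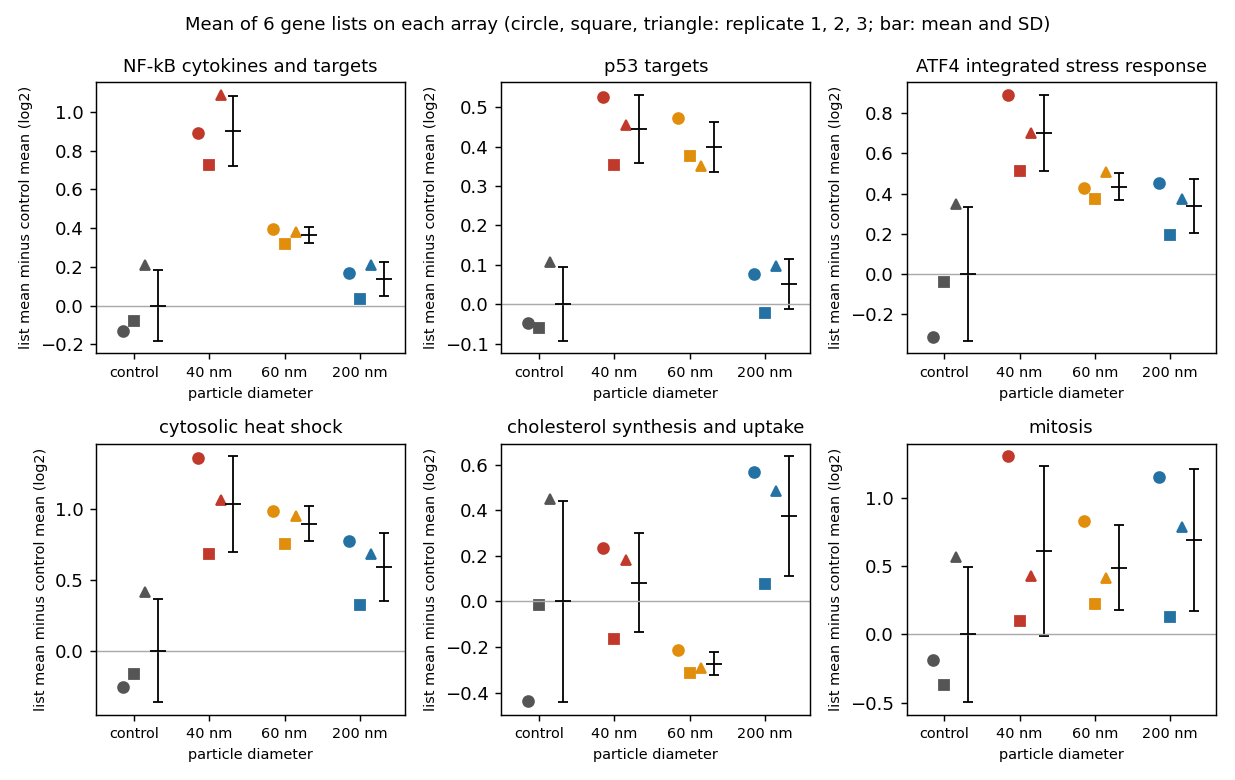
Mean of the measured genes of 6 lists on each of the 12 arrays, minus the control mean (log2), by group, with the replicate number as the marker and the bar as mean and SD (n = 3). The NF-kB list lies at 0.90 ± 0.18 at 40 nm, 0.36 ± 0.04 at 60 nm and 0.14 ± 0.09 at 200 nm, while the mitosis list has an SD of 0.50 in control cells.

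The comparison of 60 nm particles with medium only asks the same question for the middle size. The genes that rose at 40 nm had smaller values at 60 nm: FBXO32 0.90 (SE 0.13), RND3 0.83, IL1B 0.70 (SE 0.25), MMP1 0.64 (SE 0.31), G0S2 0.50, DDIT3 0.50 (SE 0.10), MMP3 0.38, KTN1 0.22, ITGA2 0.20, IL6 0.12 (SE 0.15) and SAT1 0.12. CXCL8 stood at 1.51 (SE 0.58), MDM2 at 1.09 (SE 0.23), CDKN1A at 0.75 (SE 0.19), SQSTM1 at 0.86 (SE 0.21), HMOX1 at 0.48 (SE 0.16), HSPA1A at 1.02 (SE 0.54) and HMGCS1 at -0.26 (SE 0.59). Besides FBXO32, the smallest p-values belonged to small RNA genes: MIR548G at -2.74 (SE 0.47), MIR548D1 at -2.24 (SE 0.40), MIR3613 at -1.55 (SE 0.28) and SNORD115-25 at 0.63 (SE 0.12). By limma 0 of 40517 probe sets passed, with a smallest adjusted p of 0.878, and 2019 had an unadjusted p under 0.05 (363 higher, 1656 lower). The total was near the 2025.85 that chance gives, but most were lower, and the median change over all probe sets was -0.047. The total alone therefore does not show that they came by chance.

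No single gene passed at 60 nm, while 15 of 25 lists passed with the preset correlation, 14 higher and 1 lower. All 19 p53 targets were positive with a mean of 0.40, and the list mean relative to control was 0.40 ± 0.06 against an SD of 0.09 in controls (camera adjusted p 2.07e-08). Of 15 heat shock genes, 14 were positive with a mean of 0.90, with HSP90AB1 at 2.48 and DNAJA1 at 2.05 (camera adjusted p 1.34e-11). Of 25 ATF4 genes, 23 were positive with a mean of 0.44, with the transfer RNA synthetase AARS1 at 1.30 and the serine enzyme PSAT1 at 0.99 (camera adjusted p 1.70e-09). These 3 lists held with an estimated correlation, with adjusted p of 0.00507 for p53 targets, 0.0194 for heat shock and 0.0322 for ATF4. The other 12 passing lists did not. NF-kB targets had a mean of 0.36 with 22 of 23 positive and ICAM1 at 1.26 (camera adjusted p 4.43e-06; adjusted p = 0.0697 with an estimated correlation). Lysosome genes had a mean of 0.58 with 24 of 25 positive and PSAP at 1.86 (camera adjusted p 1.34e-11; adjusted p = 0.0970 with an estimated correlation). Interferon genes had a mean of 0.20 with 26 of 28 positive and IFIT1 at 0.68 (camera adjusted p 8.34e-05; adjusted p = 0.252 with an estimated correlation). Metallothioneins had a mean of 0.23 with 8 of 8 positive and MT1F at 0.50 (camera adjusted p 0.00244; adjusted p = 0.252 with an estimated correlation).

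Endocytosis genes had a mean of 0.36 at 60 nm with RAB7A at 2.09 (camera adjusted p 0.00241; adjusted p = 0.265 with an estimated correlation). Hypoxia genes had a mean of 0.25 with PGK1 at 0.91 (camera adjusted p 0.00697; adjusted p = 0.291 with an estimated correlation). Autophagy genes had a mean of 0.27 with WIPI1 at 0.89 (camera adjusted p 0.000282; adjusted p = 0.295 with an estimated correlation). Mitosis genes had a mean of 0.49 with DLGAP5 at 1.33 (camera adjusted p 5.03e-05; adjusted p = 0.295 with an estimated correlation). Endoplasmic reticulum chaperones had a mean of 0.37 with CANX at 1.60 and HSPA5 at 1.55 (camera adjusted p 0.00115; adjusted p = 0.322 with an estimated correlation). Mesenchymal genes had a mean of 0.22 with TNC at 0.88 (camera adjusted p 0.0281; adjusted p = 0.429 with an estimated correlation). DNA replication genes had a mean of 0.21 with PRIM1 at 0.85 (camera adjusted p 0.0281; adjusted p = 0.606 with an estimated correlation), and their test direction turned without control replicate 1. Cholesterol synthesis genes were lower, with a mean of -0.27, 4 of 19 positive, MVD at -0.90 and TM7SF2 at -0.86 (camera adjusted p 0.0256; adjusted p = 0.373 with an estimated correlation). By limma 0 genes of any list passed over all genes, and 2 ATF4 genes, 2 p53 targets and 1 autophagy gene passed when adjusted over the list alone. The 10 other tested lists had camera adjusted p of 0.0811 or more, 0.0811 being that of NRF2 targets (mean 0.15). In junction genes (mean 0.09, median -0.00) and leukocyte markers (mean 0.12, median -0.01) the mean and test were positive and the median negative, in fibroblast markers the mean (-0.02) and test were negative and the median (0.02) positive, and in endothelial markers the mean was 0.07 and the median -0.03. With the spike-in mean as a covariate, camera adjusted p rose to 0.971 for DNA replication, 0.368 for mesenchymal genes and 0.101 for autophagy and hypoxia.

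The comparison of 200 nm particles with medium only asks about the largest size. At 200 nm the genes that rose at 40 nm had changes of 0.46 or less: MMP1 at 0.14 (SE 0.31), MMP3 at 0.05, IL1B at 0.23 (SE 0.25), IL6 at -0.02 (SE 0.15), ITGA2 at 0.10, SAT1 at 0.01, RND3 at 0.20, G0S2 at 0.24, KTN1 at 0.11, DDIT3 at 0.05 (SE 0.10) and FBXO32 at 0.46 (SE 0.13). CXCL8 stood at -0.06 (SE 0.58), HSPA5 at 1.75 (SE 0.80), HMGCS1 at 0.88 (SE 0.59), HSPA1A at 0.65 (SE 0.54), SQSTM1 at 0.37 (SE 0.21), CDKN1A at -0.15 (SE 0.19) and HMOX1 at 0.08 (SE 0.16). The smallest p-values belonged to MIR1264 at -0.65 (SE 0.13), C6orf163 at -0.48, GNAO1-AS1 at -0.46, MIR559 at -0.42 and PIERCE2 at -0.41. The last 4 had group means inside the range of the background rows. By limma 0 of 40517 probe sets passed, with a smallest adjusted p of 0.706, and 2411 had an unadjusted p under 0.05 (332 higher, 2079 lower). The median change over all probe sets was -0.050. Without control replicate 3 the count was 6, and without the 3 arrays of lowest spike-in mean it was 4.

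At 200 nm 12 lists passed with the preset correlation, all higher. Of 27 mitosis genes, 26 were positive with a mean of 0.69, with TPX2 at 1.93 and KIF20A at 1.88 (camera adjusted p 7.93e-06), but the list mean was 0.69 ± 0.52 against an SD of 0.50 in controls. Of 31 DNA replication genes, 27 were positive with a mean of 0.47, with MCM3 and MCM6 at 1.20 (camera adjusted p 5.31e-05). Lysosome genes had a mean of 0.39 (PSAP 1.69; camera adjusted p 9.56e-05), heat shock genes 0.59 (HSP90AB1 2.23; camera adjusted p 0.000266), autophagy genes 0.29 (WIPI1 0.83; camera adjusted p 0.000340) and mesenchymal genes 0.41 (FN1 1.52; camera adjusted p 0.000389). Endocytosis genes had a mean of 0.48 (AP2B1 2.18; camera adjusted p 0.000900), endoplasmic reticulum chaperones 0.43 (CANX 1.54; camera adjusted p 0.000901), the ATF4 list 0.34 (AARS1 1.58; camera adjusted p 0.00544) and cholesterol synthesis genes 0.38 (CYP51A1 1.45; camera adjusted p 0.00821). Hypoxia genes had a mean of 0.25 (PGK1 0.91; camera adjusted p 0.0106) and metallothioneins 0.21 (MT1F 0.52; camera adjusted p 0.0107). For all 12 lists the call was lost, with adjusted p = 0.326 to 0.327 with an estimated correlation. In each of these lists the mean on control replicate 3 lay above that on 200 nm replicate 2. With the spike-in mean as a covariate and the preset correlation 13 lists passed. NF-kB targets had a mean of 0.14 (camera adjusted p 0.228) and p53 targets 0.05 (camera adjusted p 0.884). Interferon genes had a mean of -0.00 with a median of 0.02, immediate early genes -0.00 with a median of 0.02, oxidative phosphorylation genes 0.09 with a median of -0.07, fibroblast markers 0.05 with a median of -0.02 and endothelial markers 0.06 with a median of -0.03; the test direction was positive for the first 4 of these. By limma 0 genes of any list passed over all genes or when adjusted over the list alone.

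The comparison of 40 nm with 200 nm asks whether the response depended on particle size at equal mass. MMP1 was higher at 40 nm by 5.21 (SE 0.31, limma adjusted p 0.000174), MMP3 by 2.02 (SE 0.19, limma adjusted p 0.00715), IL1B by 2.02 (SE 0.25), ITGA2 by 1.89 (SE 0.23) and IL6 by 1.22 (SE 0.15), with a limma adjusted p of 0.0362 for the last 3. Outside the naming rule, and chosen after their values were seen, SAT1 was higher by 1.09 (SE 0.10, limma adjusted p 0.00715) and FBXO32 by 1.12 (SE 0.13, limma adjusted p 0.0362). The 200 nm levels of MMP1 (4.41), MMP3 (4.43), ITGA2 (4.48) and SAT1 (4.84) lay inside the range of background row means. Background therefore limits how exactly the differences of these genes are known. IL6 at 200 nm (4.89) lay at the upper edge of that range. CXCL8 stood at 3.58 (SE 0.58, limma adjusted p 0.159), MDM2 at 1.45 (SE 0.23, limma adjusted p 0.135) and DDIT3 at 0.73 (SE 0.10, limma adjusted p 0.0723). In all 11 probe sets passed, all higher at 40 nm, and 1639 had an unadjusted p under 0.05; besides these 7 genes they were 1 gene not reported here and the unnamed clusters TC11003312.hg.1 (6.59), TC11003311.hg.1 (4.82) and TC05003160.hg.1 (1.55). With the replicate number as a block over the 9 exposed arrays MMP1 kept its call (limma adjusted p 0.0175), and the other 6 genes had limma adjusted p from 0.0654 to 0.0772, among 14 calls. The count was 4, 3 and 2 without 200 nm replicates 1, 2 and 3, 7, 5 and 5 without 60 nm replicates 1, 2 and 3, 6, 5 and 7 without control replicates 1, 2 and 3, and 7 without 40 nm replicate 3.

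Inflammatory and stress groups were higher at 40 nm than at 200 nm. NF-kB targets differed by a mean of 0.76, with 21 of 23 positive and list means of 0.90 ± 0.18 and 0.14 ± 0.09; IL1B and IL6 passed over all genes and 9 when adjusted over the list alone (camera adjusted p 8.44e-17). Interferon genes differed by 0.46, with 27 of 28 positive and OAS2 at 1.19; 0 passed over all genes and 12 when adjusted over the list alone (camera adjusted p 8.44e-17). p53 targets differed by 0.40, with 18 of 19 positive and CDKN1A at 0.76; 2 passed when adjusted over the list alone (camera adjusted p 1.47e-07). These 3 lists held with an estimated correlation, with adjusted p of 0.00525 for NF-kB and p53 targets and 0.0232 for interferon genes. With the replicate number as a block over the 9 exposed arrays and an estimated correlation, all 3 lost their call. The camera adjusted p was then 0.120 for NF-kB targets, 0.0782 for p53 targets and 0.189 for interferon genes. The ATF4 list differed by 0.37, with STC2 at 1.18 and 2 genes past the threshold when adjusted over the list alone (camera adjusted p 2.72e-07; adjusted p = 0.0537 with an estimated correlation). Lysosome genes differed by 0.42, with CTSL at 1.26 and 3 genes past it when adjusted over the list alone (camera adjusted p 1.29e-05; adjusted p = 0.254 with an estimated correlation). Metallothioneins differed by 0.26 (camera adjusted p 0.0133), and immediate early genes by 0.09 with CCN1 at -1.53 and 3 genes past the threshold, 2 higher and 1 lower, when adjusted over the list alone (camera adjusted p 0.00419); for both, adjusted p = 0.254 with an estimated correlation.

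Heat shock genes differed by 0.44 with HSPH1 at 1.59 (camera adjusted p 0.0427) and hypoxia genes by 0.19 with P4HA1 at 0.72 (camera adjusted p 0.0355); for both, adjusted p = 0.318 with an estimated correlation. Cholesterol synthesis genes were lower at 40 nm than at 200 nm by a mean of -0.29 with DHCR7 at -0.73 (camera adjusted p 0.0154; adjusted p = 0.318 with an estimated correlation). Fibroblast markers were lower by -0.21 with THY1 at -0.64 (camera adjusted p 0.0126; adjusted p = 0.106 with an estimated correlation). Of these markers DCN, POSTN and FAP had group means inside the range of the background rows. All airway secretory markers lay inside that range too and are not read as changed. They had a mean of -0.09 with MUC1 at -0.19 (camera adjusted p 0.0380; adjusted p = 0.254 with an estimated correlation). With the replicate block over the 9 exposed arrays the secretory markers lost their call (camera adjusted p 0.0642) and epithelial junction genes, lower at 40 nm, had a camera adjusted p of 0.0279 against 0.0592 (adjusted p = 0.353 with that block and an estimated correlation). The mean and median differed in sign in mesenchymal genes (0.12 and -0.06, test direction negative, MMP1 being the 1 that passed), oxidative phosphorylation genes (0.00 and -0.02), DNA replication genes (-0.12 and 0.00), leukocyte markers (0.04 and -0.03) and endothelial markers (0.02 and -0.03); the test direction was negative in the 4 of these that were tested. Of airway basal cell markers, ITGB4 at -1.18 passed when adjusted over the list alone.

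The comparison of 40 nm with 60 nm asks whether the smaller step in size separated the responses. MMP1 was higher at 40 nm by 4.71 (SE 0.31, limma adjusted p 0.000509), SAT1 by 0.97 (SE 0.10, limma adjusted p 0.0260) and MMP3 by 1.69 (SE 0.19, limma adjusted p 0.0337). IL6 stood at 1.08 (SE 0.15, limma adjusted p 0.138), IL1B at 1.55 (SE 0.25, limma adjusted p 0.304) and CXCL8 at 2.01 (SE 0.58). In all 5 probe sets passed, all higher, with TC11003312.hg.1 (5.51) and TC11003311.hg.1 (4.54), and 1435 had an unadjusted p under 0.05. With the replicate number as a block over the 9 exposed arrays 0 passed by limma, with 5478 at an unadjusted p under 0.05 and limma adjusted p of 0.0773 for MMP1 and 0.104 for MMP3 and SAT1. With the block over 12 arrays 4 passed, and MMP3 and SAT1 both had a limma adjusted p of 0.0510. The count was 10 without 40 nm replicate 2, 2 without 40 nm replicate 3, 3, 2 and 2 without 60 nm replicates 1, 2 and 3, and 3 without any 1 of the controls or without 200 nm replicate 3.

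NF-kB targets were higher at 40 nm than at 60 nm by a mean of 0.54, with 20 of 23 positive, TNFAIP3 at 1.00 and 5 genes past the threshold when adjusted over the list alone (camera adjusted p 1.26e-10), and held with an estimated correlation (adjusted p 0.0432). The other 7 passing lists, all higher, did not. With the replicate number as a block over the 9 exposed arrays and an estimated correlation, NF-kB targets lost their call too (camera adjusted p 0.368). Interferon genes differed by 0.25 with OAS2 at 1.08 (camera adjusted p 1.95e-07; adjusted p = 0.295 with an estimated correlation). The ATF4 list differed by 0.27 with XPOT at 1.30 (camera adjusted p 0.0184), immediate early genes by 0.07 with DUSP6 at 0.42 and 2 genes past the threshold when adjusted over the list alone (camera adjusted p 0.0184), metallothioneins by 0.24 and hypoxia genes by 0.19 (camera adjusted p 0.0249 each); for these 4 lists, adjusted p = 0.386 with an estimated correlation. Cholesterol synthesis genes differed by 0.36 with HMGCS1 at 1.14 (camera adjusted p 0.0249; adjusted p = 0.423 with an estimated correlation) and lysosome genes by 0.23 with LAMP2 at 0.91 (camera adjusted p 0.0250; adjusted p = 0.600 with an estimated correlation). With the replicate block over the 9 exposed arrays DNA replication and autophagy genes also passed with the preset correlation (camera adjusted p 0.0333 and 0.0125, against 0.203 and 0.122). With that block and an estimated correlation they did not (adjusted p 0.622 and 0.368). The mean was positive and the median and test negative in heat shock (0.14 and -0.03), endocytosis (0.05 and -0.07), junction (0.03 and -0.06) and ribosomal protein genes (0.01 and -0.01) and in leukocyte markers (0.00 and -0.03); in endothelial markers the mean was 0.00 and the median -0.03.

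The comparison of 60 nm with 200 nm covers the upper step in size. All 19 cholesterol synthesis and uptake genes were lower at 60 nm, with a mean of -0.65 and a median of -0.66, among them CYP51A1 at -1.29 (SE 0.89), HMGCS1 at -1.14 (SE 0.59), SQLE at -1.12 (SE 0.70) and MSMO1 at -1.06 (SE 0.63) (camera adjusted p 4.51e-12; adjusted p = 0.0550 with an estimated correlation). The list mean relative to control was -0.27 ± 0.05 at 60 nm and 0.38 ± 0.26 at 200 nm, with an SD of 0.44 in control cells. p53 targets were higher at 60 nm by 0.35, with 18 of 19 positive, MDM2 at 1.27 (SE 0.23), CDKN1A at 0.90 (SE 0.19) and 2 genes past the threshold when adjusted over the list alone (camera adjusted p 3.56e-11), and held with an estimated correlation (adjusted p 0.00159). Interferon genes were higher by 0.20 with IFI27 at 1.14 (camera adjusted p 1.50e-06), the ATF4 list by 0.10 with NUPR1 at 0.67 and 2 genes past the threshold when adjusted over the list alone (camera adjusted p 0.000204), and heat shock genes by 0.30 with HSP90AA1 at 0.85 (camera adjusted p 0.000572); for these 3 lists, adjusted p = 0.151 with an estimated correlation. NF-kB targets were higher by 0.23 with CXCL8 at 1.58 (camera adjusted p 4.34e-05; adjusted p = 0.142 with an estimated correlation) and lysosome genes by 0.19 with CTSD at 0.69 (camera adjusted p 0.00146; adjusted p = 0.609 with an estimated correlation). DNA replication genes were lower by -0.26 with CHAF1B at -0.59 (camera adjusted p 0.00146), and mesenchymal genes by -0.20 with THBS1 at -1.17 (camera adjusted p 0.0438); for both, adjusted p = 0.697 with an estimated correlation.

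Among single genes the smallest p-values between 60 nm and 200 nm belonged to ABCG1, a cholesterol exporter, at 0.25 (SE 0.05), PIERCE2 at 0.37 (SE 0.07), SNORD115-25 at 0.59 (SE 0.12), FOLR3 at 0.31 (SE 0.06) and MDM2. All but MDM2 had group means inside the range of the background rows. By limma 0 of 40517 probe sets passed, with a smallest adjusted p of 1, and 802 had an unadjusted p under 0.05, fewer than the 2025.85 that chance gives. This fit has no term for the replicate number, which was taken to pair the exposed arrays, so the test may be too strict here. With the replicate block over the 9 exposed arrays mitosis genes, lower at 60 nm by -0.20, passed with the preset correlation (camera adjusted p 0.0121 against 0.229) and not with an estimated correlation (adjusted p 0.716). Inflammasome genes had a mean of -0.00 with a median of 0.06 and a positive test direction.

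All 11 genes that rose at 40 nm had changes ordered 40 nm over 60 nm over 200 nm. They were picked for their value at 40 nm, which favours the first place. Between 60 and 200 nm 0 probe sets passed by limma. At these sizes MMP3 (4.77 and 4.43) and ITGA2 (4.58 and 4.48) lay inside the range of the background row means. The order is therefore not read as a graded trend with size. A moderated F test in limma for any difference among the 4 groups passed for 7 probe sets, and among the 3 sizes for 5; with the replicate block over the 9 exposed arrays the latter count was 3. Across 15836 genes, which are not independent replicates, changes from control correlated at 0.885 between 40 and 60 nm, 0.845 between 40 and 200 nm and 0.883 between 60 and 200 nm. In 100 simulated sets of unchanged groups, with the centred arrays dealt at random to groups, the median correlations were 0.646, 0.651 and 0.463. The central 95 percent ran from -0.705 to 0.944, from -0.685 to 0.961 and from -0.671 to 0.965, around the observed values. Ranges this wide leave open whether the sizes share a response. Independent noise with a shared control group gave correlations of 0.505, 0.501 and 0.506. The covariances were 0.137, 0.161 and 0.110 against simulated means of 0.0429, 0.0422 and 0.0469, differences of 0.0945, 0.119 and 0.0630. The upper limits of the central 95 percent of simulated covariances, 0.195, 0.203 and 0.249, lay above the observed ones. With 3 control arrays the controls could not be split with 2 in each part, so the part of this difference that comes from shared controls was not separated. The random groups also did not keep the pairing of exposed arrays by replicate number, so the part that comes from that pairing was not separated either. By limma 0 probe sets passed against control at 60 nm and 0 at 200 nm, so the overlap of calls between sizes could only be 0 and tells nothing.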

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

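The tests of the 3 patterns weighed here were chosen after the results were seen, and so were the splits within replicate numbers and the limit of the list results to those that passed with both correlations; the counts over other splits of the arrays were planned.

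These results stand out because the effects of particles of different size differed by a direct test of the difference without pairing. Between 40 and 200 nm the log2 difference was 5.21 for MMP1, 2.02 for IL1B, 2.02 for MMP3, 1.89 for ITGA2, 1.22 for IL6, 1.12 for FBXO32 and 1.09 for SAT1. Between 40 and 60 nm it was 4.71 for MMP1, 1.69 for MMP3 and 0.97 for SAT1. With the replicate number as a block over the 9 exposed arrays only MMP1 between 40 and 200 nm kept its call among these 10 (limma adjusted p 0.0175). The others had limma adjusted p from 0.0654 to 0.104. With only the 2 groups compared, MMP1 had a limma adjusted p of 0.0595 between 40 and 200 nm and 0.428 between 40 and 60 nm. The 200 nm levels of MMP1 (4.41), MMP3 (4.43), ITGA2 (4.48) and SAT1 (4.84) lay inside the range of background row means, 3.21 to 4.89. So did MMP3 at 60 nm (4.77), and the sizes of these differences are not known exactly. IL6 at 200 nm (4.89) and MMP1 at 60 nm (4.90) lay at the upper edge of that range. Among lists that passed with both the preset and an estimated correlation, NF-kB targets differed by a mean of 0.76 between 40 and 200 nm and by 0.54 between 40 and 60 nm. Interferon genes differed by 0.46 between 40 and 200 nm, and p53 targets by 0.40 between 40 and 200 nm and by 0.35 between 60 and 200 nm. With the block over the 9 exposed arrays and an estimated correlation, of these 5 list differences p53 targets between 60 and 200 nm passed (adjusted p 0.0365), and the other 4 had adjusted p from 0.0782 to 0.368.

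NF-kB, interferon and p53 targets, which passed with both correlations, and the ATF4 list, which passed with the preset one, were higher at 40 nm than at 200 nm; the group means ran 40 nm over 60 nm over 200 nm, in 3 of 3 replicate numbers for NF-kB and interferon and in 2 of 3 for ATF4 and p53, and the p53 step from 40 to 60 nm was 0.05 (camera adjusted p 0.569), with the opposite test direction after quantile or cyclic loess normalization. At equal spike-in mean the difference between 40 and 200 nm was 0.75 (95% interval 0.48 to 1.02) for NF-kB targets, 0.435 (0.19 to 0.68) for interferon genes and 0.38 (0.27 to 0.48) for p53 targets, which argues against the spike-in gradient as the whole source of these. For the ATF4 list it was 0.37 (-0.02 to 0.75) before the correction and 0.33 (-0.03 to 0.69) after it, and as the interval held 0 from the start this test decides nothing about the gradient there. Within replicate numbers the difference had an exact permutation p of 0.00926 for NF-kB targets and 0.00926 for interferon genes, the smallest that 216 arrangements give, and of 0.0185 for the ATF4 list and 0.0185 for p53 targets, with 40 nm above 200 nm in 3 of 3 numbers for each. These lists were picked for this difference on the same arrays, and the permutation p-values are not adjusted, so they are no independent support. With the replicate block over the 9 exposed arrays and an estimated correlation, the calls were lost. The camera adjusted p was then 0.12 for NF-kB targets, 0.189 for interferon genes, 0.0782 for p53 targets and 0.12 for the ATF4 list. Particle size remains a hypothesis for the difference in NF-kB, interferon and p53 targets, found on these same data. Whether size itself, particle number or surface at equal mass would carry this difference was not tested.

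Mitosis and DNA replication genes stood higher in the exposed groups than in controls. Over 9 exposed and 3 control arrays the exact permutation p was 0.0773 for mitosis and 0.159 for DNA replication, with control replicate 3 inside the exposed range, so exposure stays open. The mitosis score fell as the spike-in mean rose within groups, with a slope of -0.68 (SE 0.12), and at equal spike-in mean its difference changed from 0.61 (SE 0.41) to 0.19 (SE 0.19) at 40 nm, from 0.49 to 0.15 (SE 0.19) at 60 nm and from 0.69 to 0.40 (SE 0.19) at 200 nm, so the array gradient is a candidate source of part of this shift; the intervals held 0 before the correction as well as after it. For DNA replication the values at equal spike-in mean were 0.13 (SE 0.25), 0.035 (SE 0.25) and 0.32 (SE 0.24), and because the slope interval of -0.711 to 0.0112 holds 0, the gradient cannot be told apart from exposure there. With the spike-in mean as a covariate the mitosis list kept its camera call at 60 and 200 nm and lost it at 40 nm. The DNA replication list kept its call at 200 nm and lost it at 40 and 60 nm. Without the covariate none of these calls held with an estimated correlation.

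Cholesterol synthesis genes stood lower at 60 nm than at 200 nm. At equal spike-in mean the difference was -0.66 (95% interval -1.15 to -0.18), which argues against the gradient as the whole source. Leaving out each of the 6 arrays brought it no nearer to 0 than -0.55, which argues against a single array. The 60 nm array lay below the 200 nm array in 3 of 3 replicate numbers (-0.78, -0.39 and -0.78), with an exact permutation p of 0.00926 within numbers, the smallest that 216 arrangements give. The list was picked for this difference on the same arrays, and the permutation p is not adjusted, so it is no independent support. Particle size remains a hypothesis for this difference, found on these same data. The list missed the threshold with an estimated correlation (camera adjusted p 0.0550). It also missed it with that correlation and the replicate block over the 9 exposed arrays (camera adjusted p 0.0738). The score did not follow the order of sizes: relative to control the 40 nm arrays (-0.17 to 0.23) lay above the 60 nm arrays (-0.31 to -0.21). The control arrays ran from -0.44 to 0.45 and so covered the 60 nm arrays.

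Each comparison of 3 with 3 arrays allows 10 splits, too few for a share under 0.05. For probe sets, the real split and the highest of the other splits gave 17 and 9 calls for 40 nm against control, 0 and 0 for 60 nm, 0 and 4 for 200 nm, 11 and 0 for 40 against 200 nm, 5 and 0 for 40 against 60 nm, and 0 and 0 for 60 against 200 nm. At least as many calls as the real split came from 1, 10, 10, 1, 1 and 10 of the 10 splits in that order, the real one included. For lists the real and highest other counts were 16 and 13, 15 and 13, 12 and 12, 12 and 11, 8 and 10, and 9 and 8, with 1, 1, 2, 1, 2 and 1 of 10 splits reaching the real count. Between sizes, where the replicate numbers pair the arrays, the splits that like the real one part all 3 pairs reached at most 5, 6 and 4 lists and 0 probe sets, while the others keep 1 or more pairs together.

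For the F test among 4 groups, 7 of 100 drawn splits, the real one included, gave at least the real 7 calls, with 6084 as the highest other, so chance was not excluded. Among the 3 sizes 8 of 100 gave at least the real 5, with 439 as the highest other, and chance was not excluded; these splits ignore the replicate numbers. Of the 36 splits with 1 array of each number in each group, 4 gave at least the real 5, with 5 as the highest other. These 4 keep the 3 arrays at 40 nm together, and with them any difference of 40 nm from the other sizes. This count therefore neither excludes chance nor speaks for it. With the replicate block over the 9 exposed arrays 1 of the 36, the real one, gave at least the real 3, with 0 as the highest other. That is the smallest share that 36 splits can give. It rests on 3 calls, on splits chosen after the results were seen and on a pairing read from these same arrays, so it does not exclude chance. The splits with the most calls put replicate 1 of the 3 exposed groups together, which points to a structure of the arrays that follows that number and the low spike-in means. Outside the comparisons, 0 of 1530 control rows and 0 of 1465 probe selection regions or junctions passed against control by limma, with a smallest adjusted p of 0.0974.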

How the results depend on the processing

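The alternatives with the spike-in mean, cyclic loess, weights estimated gene by gene, the 3 arrays of lowest spike-in mean left out, and the block over 9 arrays, with either correlation for lists, were added after the data were seen; the others were planned. Where no cause is named, the cause was not tested. Counts follow the order 40 nm, 60 nm and 200 nm against control, 40 against 200 nm, 40 against 60 nm and 60 against 200 nm, with main values of 17, 0, 0, 11, 5 and 0 probe sets and 16, 15, 12, 12, 8 and 9 lists. MMP1 at 40 nm against control kept its call in all 27 alternatives (adjusted p 4.19e-07 to 0.0488), MMP3, FBXO32 and SAT1 lost it in 2, IL1B in 6 and the other 7 genes in 10 to 17. Between 40 and 200 nm, of 28 alternatives, MMP1 lost its call in 1, SAT1 in 5 and MMP3 in 6. IL1B, ITGA2 and FBXO32 lost it there in 17 and IL6 in 18. Between 40 and 60 nm MMP1 lost its call in 2 of 28, SAT1 in 13 and MMP3 in 18. The 60 nm count was 0 by limma in every alternative except array weights, with 614 to 8785 in those others at an unadjusted p under 0.05. The offsets of 1 and 64, the robust prior, the prior without trend and the fold change of at least 2 kept every count within 1.5 times. With the offset of 64, however, 7 of the 22 calls of named genes were lost. Over all alternatives the lowest change at 40 nm against control was 3.35 for MMP1, 0.85 for MMP3 and 0.44 for SAT1. Signal near background limits dim genes: background control rows had means from 3.21 to 4.89.

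Quantile normalization gave 5 calls for 40 against 200 nm and 3 for 40 against 60 nm, with 9 lists at 60 nm, 6 at 200 nm and 2 for 40 against 60 nm. Median centring gave 7 calls for 40 against 200 nm, with 4 lists at 200 nm and 5 for 40 against 60 nm. Without a filter more probe sets were adjusted for, and 11 passed at 40 nm and 5 for 40 against 200 nm; with the 60 percent filter the F test among sizes gave 8. Array weights, whose estimate did not converge, gave 20181, 2427, 14743, 15441, 3776 and 253 calls and F tests of 25035 and 15044. Weights gene by gene gave 5405 at 40 nm, 3284 at 200 nm, 345 for 40 against 200 nm, 48 for 40 against 60 nm, and F tests of 603 and 156. The replicate block over 12 arrays gave 70 at 40 nm, where CXCL8, DNAJA1, HSP90AA1 and IFIT3 then passed. Among the named genes and the lists, it changed no call between sizes other than MMP3, SAT1 and junction genes (adjusted p 0.0253). With fewer arrays in the fit, only the groups compared, the counts were 2 at 40 nm, 1 for 40 against 200 nm, 0 for 40 against 60 nm (1417 at an unadjusted p under 0.05) and 2 for the F test among sizes. With 1 probe set per gene, and so fewer tests, they were 17 for 40 against 200 nm and 11 and 10 for the F tests.

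The spike-in covariate gave 86 at 40 nm (69 higher, 17 lower), 51 for 40 against 200 nm, 11 for 40 against 60 nm and F tests of 15 and 25. Cyclic loess gave 9 lists at 60 nm and 6 at 200 nm. Without the 3 arrays of lowest spike-in mean the counts were 11 at 40 nm, 4 at 200 nm, 5 for 40 against 200 nm, 2 for 40 against 60 nm and 2 for the F test among sizes, with 4 lists for 40 against 60 nm. The block over 9 arrays gave 0 for 40 against 60 nm and 3 for the F test among sizes, and with an estimated correlation 0, 0 and 1 lists between sizes. With an estimated correlation 2, 3, 0, 3, 1 and 1 lists passed, and with fry 9, 3, 0, 4, 1 and 1; 10 of the 72 list calls held with an estimated correlation.

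Leaving out each array in turn gave 5 (without control replicate 2) to 548 (without control replicate 3) calls at 40 nm, 0 at 60 nm, 0 to 6 (without control replicate 3) at 200 nm, 2 (without 200 nm replicate 3) to 14 for 40 against 200 nm, 2 (without 40 nm replicate 3) to 10 (without 40 nm replicate 2) for 40 against 60 nm, and 0 for 60 against 200 nm. The F tests gave 3 to 11 and 3 to 11. Lists ran from 11 to 16, 10 to 16, 7 (without control replicate 1) to 12, 8 to 14, 2 (without 40 nm replicate 3) to 10 and 7 to 9. The correlations of changes ran from 0.829 to 0.939, 0.786 to 0.917 and 0.784 to 0.954. Without control replicate 1 the DNA replication list at 60 nm reversed its direction (adjusted p 0.988), and over the arrays left out its adjusted p ran from 3.97e-05 (without control replicate 3) to that value.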
